A study of Mus musculus with 30 samples.

How the data were processed

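Gene expression was measured by RNA-seq in splenic B cells of C57BL6 wild-type mice aged 12 weeks. Marginal zone (MZ) and follicular (FO) B cells were sorted by flow cytometry after the mice had received an antibody against the receptor Notch2, or an isotype control antibody. Per the labels, MZ cells were live CD19+ CD93- CD23- cells with high CD1d, and FO cells were CD19+ CD93- CD23+ cells without CD1d. The 30 libraries fall into 8 groups. Each cell type had 4 isotype libraries, taken at 48 h and used as the control for every time. At 12 and 24 h an effect of the antibody therefore cannot be told apart from one of the sampling time. Each cell type had 4 libraries at 12 h, 3 at 24 h and 4 at 48 h after the antibody against Notch2. Groups and replicate numbers came from the sample labels. The labels neither state that the libraries of a group came from separate mice nor tie an MZ library to an FO library of the same number. P-values therefore measure the spread between these samples, which may be partly technical.

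Per the labels' protocols, cDNA was made from poly(A) RNA by template switching and cut and tagged by transposition, a procedure that keeps no strand information unless stated, and strand was not stated. Antisense partners of a gene cannot be told apart in such data. Per the submitters' processing notes, the genome build was mm10 and the tools included kallisto and limma, and per the series' design text the values were normalized with voom. Tool versions and the annotation release were not given in the sources used here. The authors deposited a table of log2 values (log2 CPM from voom) and a table of TPM for 30317 genes in the same 30 libraries. Per the deposited TPM table, the listed genes summed to between 0.936 and 0.953 of 1000000 per library, so part of each library's TPM is not listed.

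Depth was worked out from the deposited values. The offset of 0.5 counts that voom adds allowed estimated counts and library totals to be calculated back, giving 5.49 to 14.0 estimated counts per library, in units of 1000000. At most 14.2% of the estimated counts above that offset lay within 0.001 of a whole number in any library. They were therefore not treated as read counts and no count test was run. These libraries carry no molecular identifiers, so reads are not independent molecules.

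Genes with a mean TPM of at least 1 over all libraries were tested, which left 12822 genes. Of these, 8978 had a mean TPM of at least 5. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 8 groups, a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment over all genes tested. The precision weights that voom makes are not part of the table, so the trend stands in for them. Genes with an adjusted p under 0.05 were called. All fold changes of single genes are log2 differences of the deposited log2 values, and the offset makes them too small for low genes. The 12 results fixed before the data were examined are each cell type at 12, 24 and 48 h against its isotype libraries, MZ against FO under isotype, the difference between the MZ and the FO effect at each time, and differences among the 3 times within each cell type by limma's moderated F test.

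The genes named were set by a rule fixed before the data were examined. In each comparison it took the 10 largest rises and the 10 largest falls among called genes with a mean TPM of at least 5 over the groups compared and no overlap between the groups' libraries. Every library of one group then lay beyond every library of the other. Immunoglobulin and T cell receptor segments and genes known only by a model or clone name were left out. For the differences between cell types it took 5 genes each way without the condition on overlap. Notch2, Dtx1, Hes1, Hes5, Nrarp, Cr2, Cd1d1, Fcer2a, Myc and Cd93 were always included. Members of gene lists are named as examples of their list.

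There were 27 gene lists with 549 members, all fixed before the data were examined. All members were found in the table and 510 were tested. The lists covered Notch targets, Notch pathway components, MZ markers, FO markers, amino acid supply and ATF4 targets, glycolysis, sterol synthesis, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, the secretory pathway, plasma cell genes, B cell identity, immediate early genes, NF-kB targets, migration and retention, BCL2 family and survival, cell cycle and interferon response. Marker lists covered T cells, myeloid cells, dendritic cells, NK cells, red cells and platelets, stromal cells, transitional B cells and B1 cells. Some genes are in more than 1 list. Dtx1, Cr2 and Asb2 are in both the Notch target and the MZ marker list, so results of these lists are not independent. Of the genes used in the sort, Cd1d1 is in the MZ marker list and Fcer2a in the FO marker list. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, with adjustment over 189 tests, and again with an estimated correlation.

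A search of the reference transcripts (GENCODE M21, GRCm38, which is mm10) for shared words of 24 bp found 12 listed gene models made of a tandem repeat with a usual spacing of 234 bp. Their summed share of listed TPM is called the satellite share. They were found from 7 models after the values had been seen. Olfactory (1237 listed) and vomeronasal receptor genes (328 listed) served as genes with no known role in B cells. Library measures were compared by two-sided exact permutation tests, with Benjamini-Hochberg adjustment over 35 tests. Gene positions came from the same annotation.

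The fits were tested on simulated values for the same 12822 genes with 200 changed in each comparison. For a log2 change of 1, the share recovered was 58.0% for MZ at 12 h, 53.6% at 24 h and 58.4% at 48 h. It was 58.5%, 69.1% and 65.2% for FO at those times and 65.3% for MZ against FO. For a log2 change of 0.5 it lay between 14.7% (FO at 24 h) and 36.8% (FO at 12 h). False calls made up 0.86% to 7.20% of calls. Lists of 30 genes shifted by 0.50 were found in 7 of 7 simulated comparisons and unshifted lists in 0. Noise was drawn independently for each gene and library. These values therefore leave out error from correlated genes and from shifts shared across a library.

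Alternatives fixed in advance were log2 TPM with a pseudocount of 1, 0.1 or 5, no filter on low values, a mean TPM of at least 5, no mean-variance trend, sample weights, library medians set equal, quantile normalization, the replicate number as a block, only the groups compared, and leaving out each library. Alternatives added after seeing the data were the log2 satellite share of each library as a covariate (below, the satellite covariate), removal of the satellite models from TPM, voom weights from the estimated counts, and subsets of libraries by satellite share. Overlaps between comparisons that share isotype libraries were set beside 100 simulated draws without effects. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes are reported at gene level only, since the tables do not separate transcripts. Listed genes with near-identical copies (Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6, Pgam1-ps2, Rpl15-ps3, the double entry Txnrd2 and TXNRD2, and the gene pairs Hba-a1 and Hba-a2 and Hspa1a and Hspa1b) are reported as uncertain.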

Results

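The data describe MZ and FO B cells of the mouse spleen under an isotype control antibody and 12, 24 and 48 h after an antibody against Notch2, a receptor that MZ B cells are known to need. Library totals, in units of 1000000 estimated counts, averaged 10.8 ± 0.670 (SD, n = 4) in isotype MZ libraries, 10.7 ± 1.01 (n = 4) at 12 h, 10.2 ± 0.280 (n = 3) at 24 h and 7.86 ± 0.464 (n = 4) at 48 h. In FO libraries they averaged 10.6 ± 2.49 (n = 4), 10.4 ± 2.46 (n = 4), 6.55 ± 1.06 (n = 3) and 7.59 ± 1.05 (n = 4). All libraries lay between 5.49 and 14.0 of these units. Totals are estimated counts behind the deposited values, so no counting interval was computed for single genes. All adjusted p-values of genes below are from limma with Benjamini-Hochberg adjustment over 12822 genes, and all log2 changes of genes are on the deposited log2 scale.

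The share of listed TPM taken by 12 models of satellite repeat differed between the groups. These models lie on chromosome 9 near its start (first base 3000922, last base 3038316), on chromosome 2 (98662237 to 98667301) and on chromosome 14 (19415857 to 19418930) of GRCm38. The share was 2.65% ± 1.67 (SD, n = 4) in isotype MZ libraries, 10.2% ± 1.93 (n = 4) at 12 h, 17.0% ± 8.60 (n = 3) at 24 h and 35.3% ± 11 (n = 4) at 48 h. In FO libraries it was 12.4% ± 11.1 (n = 4), 16.5% ± 8.69 (n = 4), 31.9% ± 2.36 (n = 3) and 28.6% ± 13.2 (n = 4). Of estimated counts, the scale of the gene tests, these models took 0.0821% to 1.36% in isotype MZ libraries, 2.95% to 4.37% at 12 h, 3.37% to 10.4% at 24 h and 10.6% to 25.1% at 48 h, and in FO libraries 0.570% to 8.12%, 2.00% to 8.74%, 10.6% to 12.9% and 4.6% to 19.1%. In share of TPM, every treated MZ library lay above every isotype MZ library at each time, with an exact permutation p of 0.0286 for each time, the smallest that 4 against 4 or 3 against 4 libraries can give, and 0.0910 after adjustment. In FO the exact permutation p was 0.543 at 12 h, 0.0571 at 24 h and 0.114 at 48 h. Summed TPM of olfactory receptor genes, with satellite models left out, was 60.3 ± 28.5 in isotype MZ libraries and 111 ± 6.59, 202 ± 113 and 370 ± 15.4 at 12, 24 and 48 h. In FO libraries that sum was 211 ± 174, 225 ± 97.3, 697 ± 76.1 and 484 ± 246. With satellite models left out of TPM, mitochondrial transcripts took 2.35% ± 0.238 in isotype MZ libraries and 2.54% ± 0.191 at 48 h (exact permutation p = 0.286).

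**Figure D1:**
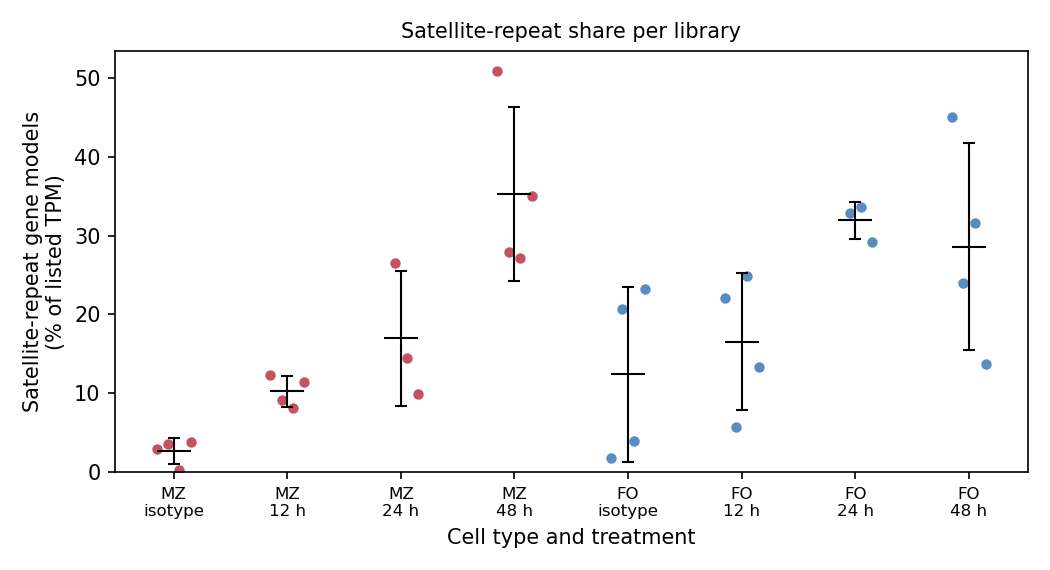
Share of listed TPM taken by 12 satellite repeat models (y axis, percent) in each of the 8 groups (x axis), with a dot per library and the mean ± SD. Isotype MZ libraries lay between 0.227% and 3.87%, and MZ libraries at 48 h between 27.2% and 50.9%.

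MZ and FO B cells were first compared under isotype, which gives the difference without the antibody against Notch2, at 48 h. Known Notch targets stood higher in MZ cells. Dtx1, a ubiquitin ligase of the Notch pathway, was at 610 ± 26.5 TPM in MZ and 109 ± 13.1 in FO libraries (SD, n = 4 each; log2 difference 2.56, SE 0.0902, adjusted p = 9.7e-19). The repressors Hes5 (3.55) and Hes1 (1.35), Myc (1.89), which drives growth, and the complement receptor Cr2 (1.47) were higher too. Nrarp, a feedback inhibitor of Notch, was lower in MZ (log2 difference -1.52) at 1.04 against 3.15 TPM. Notch2 itself was at 8.39 ± 1.69 TPM in MZ and 10.4 ± 2.51 in FO libraries (log2 difference -0.24, SE 0.188, adjusted p = 0.337). Of the 7 Notch targets tested, 6 were higher and 1 lower in MZ, with the same counts adjusted over the list alone (camera adjusted p = 9.96e-09; adjusted p = 0.00134 with an estimated correlation).

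Among the genes with the largest differences under isotype, those higher in MZ were the chemokine scavengers Ackr3 (5.19) and Ackr2 (4.51), Rap1gap (5.18), which turns off the GTPase Rap1, the tetraspanin Tspan15 (4.96), Ceacam2 (4.72), the ubiquitin ligase subunit Asb2 (4.63), the sphingosine phosphate receptor S1pr3 (4.56), the protease inhibitor Serpine2 (4.55) and the lipase Lipc (4.50). Pgam1-ps2, a pseudogene with an active near-identical copy and therefore uncertain, differed by 4.96 (SE 1.43) and lost its call with the satellite covariate at 4.35 (SE 1.64). Lower in MZ were the transcription factor Mef2c (-5.98; 0.494 ± 0.434 against 21.8 ± 3.48 TPM), the phosphodiesterase Pde2a (-5.29), Ces5a (-4.19), Crisp3 (-4.13), the kinases Mapk12 (-3.78) and Mapk11 (-3.41), Rgl1 (-3.37), Kctd14 (-3.18) and Rbpms (-3.02). Fcer2a, which encodes CD23 (-4.16), Cd1d1 (3.19) and Cd93 (-1.98) served in the sort, so their differences are no finding. With that covariate Ces5a stood at -2.36, Pde2a at -3.74 and Cd93 at -0.92, all still called. Of 19 MZ markers, 18 were higher and 0 lower, and of 12 FO markers 11 were lower and 1 higher, with the same counts adjusted over the list alone (adjusted p = 3.82e-05 and 0.0138 with an estimated correlation). These counts and tests include Cd1d1 among the MZ markers and Fcer2a among the FO markers, both used in the sort. All 38 ribosomal protein genes were higher in MZ, as were 38 adjusted over the list alone (camera adjusted p = 5.06e-17; adjusted p = 0.323 with an estimated correlation). In all, 2153 genes were higher and 2131 lower in MZ. The total of 4284 became 2927 with the satellite covariate, with 2525 genes called the same way in both. Satellite models left out of TPM gave 1399 higher and 3518 lower, and the replicate number as a block within cell type, a number that the labels do not tie to a mouse, gave 1530 calls.

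At 12 h after the antibody, Notch targets were lower in MZ cells. Dtx1 fell from 610 ± 26.5 to 110 ± 8.37 TPM (log2 change -2.44, SE 0.0902, adjusted p = 1.61e-17), Hes1 from 141 ± 22.5 to 17.5 ± 1.46 (-2.96, SE 0.171, adjusted p = 1.06e-12) and Hes5 from 91.9 ± 4.41 to 15.7 ± 2.65 (-2.52, SE 0.223, adjusted p = 9.61e-09; n = 4 for each group). Myc fell by 1.36, Cr2 by 1.07 and the lipid antigen presenter Cd1d1 by 0.77. Of the 7 Notch targets tested, 6 fell, as did 6 adjusted over the list alone (camera adjusted p = 2.4e-16; adjusted p = 3.82e-05 with an estimated correlation). The target outside these was Nrarp (log2 difference 0.00, adjusted p = 0.999), and Notch2 differed by 0.22 (adjusted p = 0.503) and Cd93 by 0.75 (adjusted p = 0.309). Dtx1 lies on chromosome 5 (120680202 to 120711927, minus strand), Hes1 on chromosome 16 (30064384 to 30067796, plus strand), Hes5 on chromosome 4 (154960923 to 154962371, plus strand), Cr2 on chromosome 1 (195136811 to 195176716, minus strand), Myc on chromosome 15 (61985391 to 61990374, plus strand) and Notch2 on chromosome 3 (98013527 to 98150361, plus strand) of GRCm38. All are annotated as protein-coding genes, and the values are for the whole gene.

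**Figure D2:**
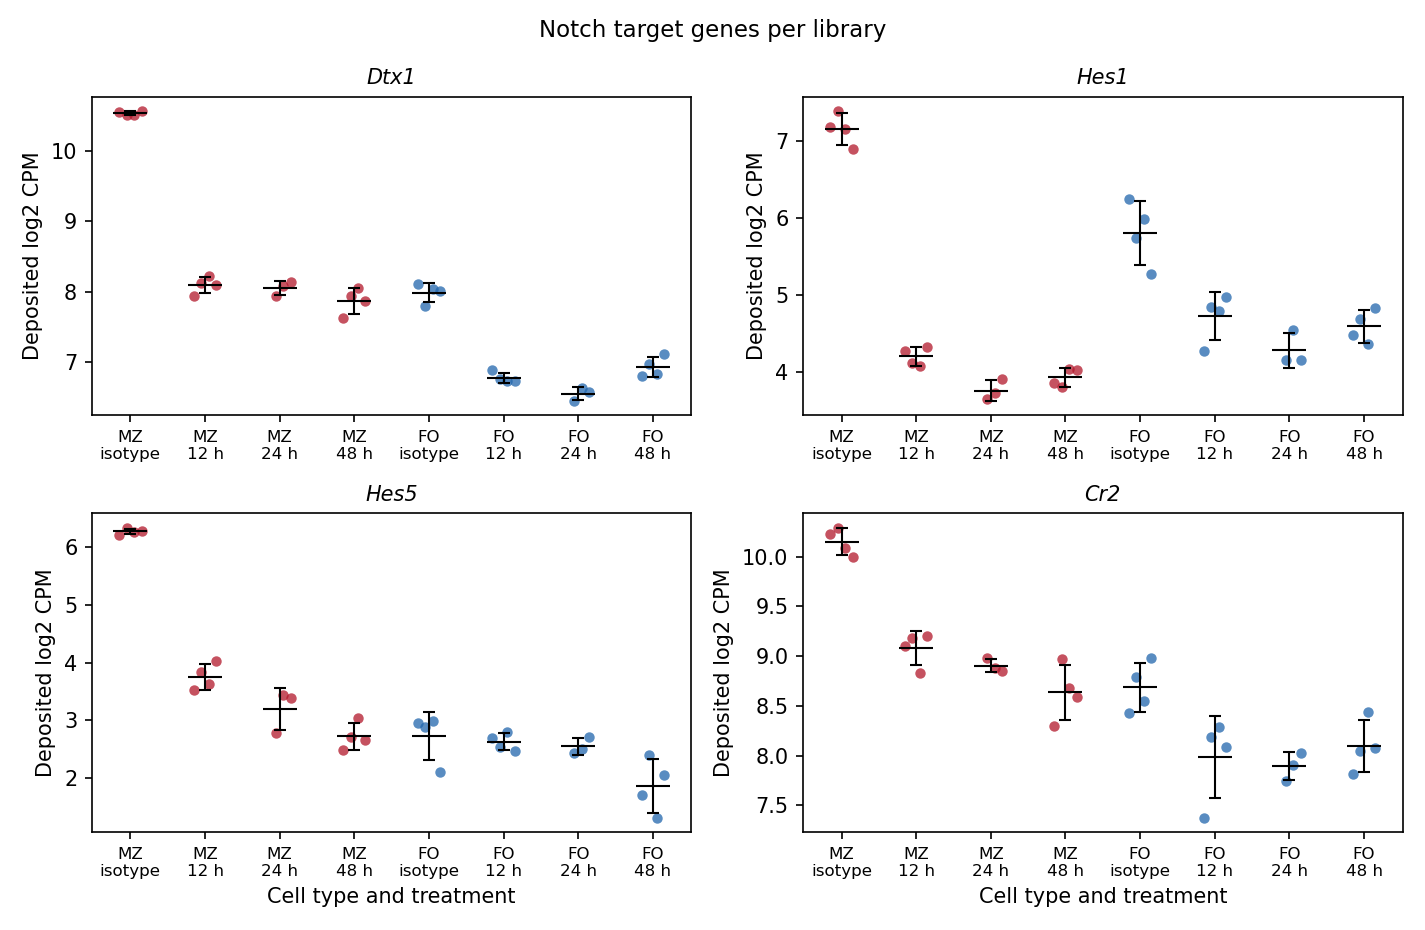
Deposited log2 CPM (y axis) of Dtx1, Hes1, Hes5 and Cr2, 1 panel per gene, in the 8 groups (x axis), with a dot per library and the mean ± SD. Dtx1 differed from isotype by -2.44 in MZ and -1.21 in FO libraries at 12 h, on the log2 scale.

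The falls at 12 h included genes that mark MZ cells, some of them also Notch targets, while genes typical of FO cells rose. Tspan15 fell from 51.3 ± 12.1 to 2.91 ± 0.857 TPM (log2 change -4.13, SE 0.307, adjusted p = 3.04e-10). This gene lies on chromosome 10 (62185396 to 62231251, minus strand). S1pr3 fell by 1.15 and Asb2, which is also a listed Notch target, by 1.19. The cannabinoid receptor Cnr2, from the migration and retention list, fell by 0.92. Of 19 MZ markers 11 fell and 0 rose, against 15 adjusted over the list alone (camera adjusted p = 2.5e-14; adjusted p = 0.00134 with an estimated correlation). Of 12 FO markers 8 rose and 1 fell, against 11 and 1 adjusted over the list alone (camera adjusted p = 3.74e-15; adjusted p = 0.0205 with an estimated correlation). They included the transcription factor Klf2 (1.29), the complement regulator Cd55 (1.28), the integrin subunit Itgb7 (1.23), the chemokine receptor Ccr7 (1.05) and Fcer2a (0.69).

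Genes of ribosome assembly and the cell cycle fell at 12 h as well. Of 34 ribosome biogenesis genes 29 fell, against 30 adjusted over the list alone, among them Polr1b (-0.99), Nop16 (-0.78) and Nop56 (-0.77) (camera adjusted p = 2.82e-24; adjusted p = 0.0086 with an estimated correlation). With the satellite covariate 12 of them fell, and their median change went from -0.60 to -0.48 (camera adjusted p = 6.69e-17). Of 32 cell cycle genes 19 fell, against 23 that fell and 1 that rose adjusted over the list alone, including the replication helicase subunits Mcm2 (-0.78) and Mcm5 (-0.65) (camera adjusted p = 2.88e-11; adjusted p = 0.109 with an estimated correlation). Of 38 ribosomal protein genes 6 fell, against 8 adjusted over the list alone (camera adjusted p = 7.23e-11; adjusted p = 0.489 with an estimated correlation), and their median change of -0.37 turned to 0.02 with the satellite covariate. Of 30 genes of oxidative phosphorylation 10 fell, against 19 adjusted over the list alone (adjusted p = 0.315 with an estimated correlation).

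Among the other large falls at 12 h were Irgm2 (-2.79), Rasl11a (-2.69), the heat shock gene Hspa1b (-2.61, uncertain), Osgin1 (-2.44), the phosphatase Alpl (-2.16) and Ccdc79 (-2.01). The largest rises were Ces5a (2.22), Rab34 (1.93), the Fc receptor Fcgr3 (1.74), Nupr1l (1.63), the cholesterol exporter Abca1 (1.63), the iron carrier Trf (1.62), the lectin Lgals3 (1.62), the intermediate filament Vim (1.5, 24.5 ± 1.88 to 68.4 ± 10.1 TPM), the complement subunit C1qb (1.45) and the Fc carrier Fcgrt (1.43). Of 14 myeloid markers 6 rose, against 6 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.000108; adjusted p = 0.171 with an estimated correlation). With the satellite covariate Ces5a stood at 0.03, Rab34 at 0.27 and Irgm2 at -2.97, none of them called, and for Irgm2 the SE went from 0.899 to 1.09. Irgm2 also lost its call without any 1 isotype MZ library, Rab34 without isotype library 3 or MZ 12 h library 4, and Ces5a without isotype library 3 or MZ 12 h library 1, 2 or 4. In all, 523 genes rose and 756 fell. The total of 1279 was 776 without isotype MZ library 3, 826 without MZ 12 h library 1, 757 with the satellite covariate (503 called the same way in both) and 582 to 653 on log2 TPM scales. Sample weights gave 2114 calls, and satellite models left out of TPM gave 762 rises and 715 falls.

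At 24 h Notch targets and MZ markers were lower in MZ cells and FO markers higher, and Lmna, Vim and Myadm were among the genes with the largest rises. Hes1 (-3.40), Hes5 (-3.08) and Dtx1 (-2.49, 104 ± 14.5 TPM, n = 3) stayed low, as did Cd1d1 (-1.28), Cr2 (-1.25) and Myc (-1.05), while Fcer2a rose by 0.95 and Nrarp differed by -0.45 (adjusted p = 0.329). Lmna, the gene of the nuclear lamins A and C (chromosome 3, 88480147 to 88509956, minus strand), rose from 1.19 ± 0.289 (n = 4) to 12.5 ± 4.38 TPM (n = 3; log2 change 3.42, SE 0.312, adjusted p = 1.19e-08). Vim (2.04) and the membrane protein Myadm (2.13) rose too, and Lmna, Vim and Myadm stood at 3.46, 2.41 and 2.34 with the satellite covariate. Of 7 Notch targets 6 fell, as did 6 adjusted over the list alone (camera adjusted p = 1.3e-14; adjusted p = 6.58e-05 with an estimated correlation). Of 19 MZ markers 14 fell, against 15 adjusted over the list alone (adjusted p = 0.00134 with an estimated correlation), and of 12 FO markers 9 rose, against 11 adjusted over the list alone (adjusted p = 0.0266 with an estimated correlation).

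Further falls at 24 h were Tspan15 (-3.95), Rasl11a (-2.59) and Ffar2 (-2.53), a receptor for short fatty acids. The pseudogenes Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6 share 1 value (-3.69) and are uncertain. Further rises were Ces5a (4.38), the carbonic anhydrases Car2 (2.73) and Car1 (2.53), Rab34 (2.61), Caps2 (2.45), the pheromone receptor gene Vmn2r55 (2.12) and the haemoglobin gene Hba-a2 (2.07, uncertain). Of 9 markers of red cells and platelets 6 rose, as did 6 adjusted over the list alone (camera adjusted p = 0.000339; adjusted p = 0.115 with an estimated correlation). Notch2 differed by 0.59 (adjusted p = 0.0427) and by 0.12 with the satellite covariate, which ended its call. That covariate also ended the calls of Cd93 (1.55, then -0.03), Rab34 (0.53), Caps2 (0.24) and Vmn2r55 (0.50), and left Ces5a called at 1.66. It ended those of Rasl11a (then -3.06, SE from 0.756 to 0.952), the Rpl35a pseudogenes (then -3.78, SE from 1.23 to 1.57), Hba-a2 (then 1.76, SE from 0.446 to 0.562) and Car1 (then 1.75, SE from 0.773 to 0.956) with larger SEs. Calls also ended without isotype MZ library 3 (Notch2, Cd93, Rasl11a, Car1 and the Rpl35a pseudogenes), MZ 24 h library 2 (Notch2, Cd93, Rasl11a, Car1 and Caps2), 3 (Cd93, Car1 and the pseudogenes) or 4 (Notch2, Rasl11a and the pseudogenes), and isotype library 2 (the pseudogenes) or 4 (Notch2 and the pseudogenes).

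Ribosomal protein genes were lower at 24 h. All 38 ribosomal protein genes fell, as did 38 adjusted over the list alone (median -0.63; camera adjusted p = 8.29e-18; adjusted p = 0.315 with an estimated correlation), and with the satellite covariate 0 of 38 did (median -0.13). Ribosome biogenesis genes fell in 17 of 34 cases, against 21 adjusted over the list alone (adjusted p = 0.205 with an estimated correlation), and cell cycle genes in 14 of 32, against 18 adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). In total 1111 genes rose and 1106 fell at 24 h. The count of 2217 was 1024 without isotype MZ library 3, 804 without MZ 24 h library 2, 1252 without MZ 24 h library 3 and 1128 without isotype library 3 and MZ 48 h library 1. With the satellite covariate it was 431 (346 called the same way in both), on log2 TPM scales 1096 to 1262 and with sample weights 3533. Log2 TPM with a pseudocount of 1 gave 433 rises and 722 falls, and satellite models left out of TPM gave 1311 and 681.

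At 48 h Notch targets and MZ markers were low in MZ cells. Dtx1 stood at 80.2 ± 16.8 TPM (log2 change -2.67, SE 0.0902, adjusted p = 1.47e-18, n = 4), Hes5 at 6.51 ± 1.60 (-3.56, SE 0.223, adjusted p = 2.04e-12) and Hes1 at 12.3 ± 1.76 (-3.23, SE 0.171, adjusted p = 5.56e-14). Cr2 had fallen by 1.51 to 219 ± 59.6 TPM, Cd1d1 by 1.69 to 118 ± 23.1 and Myc by 1.03 to 99.1 ± 28.6, while Nrarp differed by -0.60 (adjusted p = 0.088). Asb2 (-2.75), S1pr3 (-2.35), Tspan15 (-3.95) and Ffar2 (-3.21) fell. Of 7 Notch targets 6 fell, against 7 adjusted over the list alone (camera adjusted p = 1.5e-08; adjusted p = 0.00134 with an estimated correlation), and of 19 MZ markers 16 fell, as did 16 adjusted over the list alone (adjusted p = 0.0046 with an estimated correlation). Of 12 FO markers 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.23e-05; adjusted p = 0.312 with an estimated correlation). Klf2 had risen by 2.10, Cd55 by 1.74 and Itgb7 by 1.36. Fcer2a rose by 0.40 (adjusted p = 0.00332), a call that the satellite covariate ended at 0.51, where the SE went from 0.107 to 0.157.

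Members of 5 further lists were lower at 48 h. All 38 ribosomal protein genes fell, as did 38 adjusted over the list alone (median -0.91 against -0.13 for all genes; adjusted p = 0.366 with an estimated correlation). Oxidative phosphorylation genes fell in 28 of 30 cases, as did 28 adjusted over the list alone (adjusted p = 0.315 with an estimated correlation), ribosome biogenesis genes in 26 of 34, against 27 adjusted over the list alone (adjusted p = 0.26 with an estimated correlation), and cell cycle genes in 24 of 32, where 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.315 with an estimated correlation). Of 20 glycolysis genes 15 fell and 1 rose, with the same counts adjusted over the list alone, including Pgk1 (-1.05) and Ldha (-0.74) (adjusted p = 0.336 with an estimated correlation). With the satellite covariate the falls numbered 1, 2, 6, 9 and 4 in these 5 lists. Their median changes went from -0.91 to -0.24, -0.65 to -0.21, -0.63 to -0.42, -0.82 to -0.735 and -0.61 to -0.27 in that order.

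The largest rises at 48 h were a mixed group. Lmna rose to 17.8 ± 3.28 TPM (log2 change 4.17, SE 0.289, adjusted p = 1.87e-11) and stood at 4.24 with the satellite covariate. Ces5a (5.64), Khdrbs2 (4.29), Rab34 (4.04), Caps2 (3.50), Slc18b1 (3.30), Hsd3b2 (3.16), Fgd4 (3.14), Glrb (3.12) and the olfactory receptor gene Olfr613 (3.09) made up the rest. With that covariate Ces5a stood at 1.94 and stayed called, the others lost their calls, and Khdrbs2 (-1.04), Hsd3b2 (-0.42), Glrb (-0.41), Olfr613 (-0.23) and Notch2 (0.50, then -0.14) turned sign. The call of Cd93 ended too (2.22, then 0.07). Calls of Pgam1-ps2 (-6.39, then -5.17, SE from 1.43 to 2.18), Rpl15-ps3 (-3.35, then -2.53, SE from 0.638 to 0.957) and the Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6 entries (-3.77, then -3.90, SE from 1.14 to 1.75) ended with larger SEs. Notch2 also lost its call without isotype MZ library 3 or MZ 48 h library 2 or 4. Markers of red cells and platelets rose in 6 of 9 cases, as did 6 adjusted over the list alone (camera adjusted p = 0.000809; adjusted p = 0.146 with an estimated correlation), and of 14 myeloid markers 2 rose and 3 fell, against 1 and 3 adjusted over the list alone (camera adjusted p = 0.9). At 48 h 2366 genes rose and 3829 fell. The count of 6195 became 672 with the satellite covariate (582 called the same way in both) and 9575 without a filter on low values. The split into rises and falls was 2928 and 2806 with library medians set equal, 1630 and 5627 on log2 TPM with a pseudocount of 1, and 3689 and 1578 with satellite models left out of TPM.

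In FO libraries at 12 h after the antibody some Notch targets and immediate early genes were lower and myeloid markers higher. Dtx1 fell from 109 ± 13.1 to 44.9 ± 1.62 TPM (log2 change -1.21, SE 0.0902, adjusted p = 1.3e-09, n = 4 each) and Hes1 from 59.2 ± 18.0 to 26.3 ± 5.62 (-1.09, SE 0.171, adjusted p = 0.000872). Of 7 Notch targets 2 fell, against 4 that fell and 1 that rose adjusted over the list alone (camera adjusted p = 2.61e-07; adjusted p = 0.00323 with an estimated correlation). Of 19 MZ markers 2 fell, against 7 that fell and 1 that rose adjusted over the list alone (adjusted p = 0.0305 with an estimated correlation). Of 20 immediate early genes 4 fell, against 7 adjusted over the list alone: Jun (-1.05), Fos (-0.69) and the heat shock pair Hspa1b (-2.94) and Hspa1a (-2.89), which is uncertain (camera adjusted p = 2.43e-08; adjusted p = 0.0277 with an estimated correlation). Tbl1xr1 (-0.63) and the oxidase subunit Ncf2 (-0.46) fell as well.

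Of 14 myeloid markers 7 rose in FO libraries at 12 h, against 9 adjusted over the list alone (camera adjusted p = 2.46e-28; adjusted p = 6.58e-05 with an estimated correlation). They included the complement subunits C1qa (1.97), C1qb (1.96) and C1qc (1.82), Vcam1 (1.90), the lysozyme gene Lyz2 (1.32) and Emr1 (1.22). Trf (2.29), Fcgr3 (1.67), the receptor kinase Axl (1.53) and Sirpa (1.17) were the other large rises. C1qb went from 11.4 ± 1.40 to 42.6 ± 3.07 TPM and Lyz2 from 62.1 ± 13.4 to 152 ± 45.6. C1qb and Trf rose in MZ libraries at 12 h too, by 1.45 and 1.62. Whether the myeloid signal, in FO or MZ libraries, came from B cells or from other cells in the sorted samples was not tested. Differences that were not called at 12 h were -0.70 for Cr2, -0.47 for Myc, -0.10 for Hes5, 0.26 for Nrarp, 0.06 for Fcer2a, 0.03 for Cd1d1, -0.03 for Cd93 and -0.03 for Notch2 (adjusted p from 0.0756 to 0.999). The test called 26 genes, 15 higher and 11 lower, and 26 of them were also called with the satellite covariate. Without FO isotype library 3 there were 14, without FO isotype library 4 there were 15 and without FO 12 h library 2 there were 15. With only the groups compared there were 9, and with the FO libraries of at least 10% satellite share 15, and both of these ended the call of Hes1. Hspa1a, Hspa1b, Fos, Tbl1xr1, Ncf2 and Emr1 lost their calls without FO isotype library 3 or FO 12 h library 2 or 3. Further libraries ended calls too, namely FO isotype 1 (Emr1, Fos, Ncf2), 2 (Emr1, Fos, Tbl1xr1) and 4 (Fos, Hspa1a, Hspa1b, Tbl1xr1) and FO 12 h 1 (Emr1, Hspa1a, Hspa1b, Ncf2, Tbl1xr1) and 4 (Emr1, Fos, Tbl1xr1). Fcgr3 lost its call without FO isotype library 3 or 4 or FO 12 h library 1, and Axl without FO isotype library 3.

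At 24 h some Notch targets and immediate early genes were lower in FO cells. Dtx1 fell by 1.44 to 35.8 ± 2.40 TPM (SE 0.0975, adjusted p = 1.34e-10, n = 3) and Hes1 by 1.53 to 17.7 ± 2.53 (SE 0.184, adjusted p = 3.16e-05). Of 7 Notch targets 4 fell, as did 4 adjusted over the list alone, with Cr2 (-0.79) and Myc (-0.74) among them (camera adjusted p = 4.49e-06; adjusted p = 0.00774 with an estimated correlation). Not called were Hes5 (-0.19), Nrarp (-0.33), Notch2 (0.41), Cd93 (0.83), Cd1d1 (-0.09) and Fcer2a (-0.06), with adjusted p from 0.159 to 0.759. Of 20 immediate early genes 10 fell, against 14 adjusted over the list alone, including the uncertain pair Hspa1b (-3.39) and Hspa1a (-2.79) and the phosphatase Dusp1 (-0.99) (camera adjusted p = 9.05e-09; adjusted p = 0.0233 with an estimated correlation). MZ markers fell in 7 of 19 cases, against 8 that fell and 1 that rose adjusted over the list alone (adjusted p = 0.112 with an estimated correlation), and of 14 myeloid markers 5 rose, against 7 adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). Socs3 (-1.34), an inhibitor of cytokine signalling, Lcmt1 (-1.23), Timm22 (-0.99) and the double entry Txnrd2 and TXNRD2 (-1.29, uncertain) fell. Pla2g4a (3.50), Glrb (2.25), Trim52 (2.22), Ppp2r2c (2.17), Hsd3b2 (2.07), Bai3 (2.04), Zfp488 (2.02), Xpnpep2 (2.00), Mrgprc2-ps (1.99) and Hba-a1 (1.98, uncertain) rose.

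Only Dtx1, Hes1 and Dusp1 among the FO genes named at 24 h stayed called with the satellite covariate, and Hes1 lost its call with only the groups compared. With that covariate Hspa1b stood at -3.33, Hspa1a at -2.71, the Txnrd2 entries at -1.13, Socs3 at -1.06, Lcmt1 at -1.04, Timm22 at -0.91, Cr2 at -0.86 and Myc at -0.58, each with a larger SE (Hspa1b from 0.642 to 0.727). Among the rises Pla2g4a stood at 2.68, Hba-a1 at 1.88 and Ppp2r2c at 1.49, and the others lay between 0.34 (Hsd3b2) and 0.84 (Xpnpep2), with Glrb at 0.55. The 10 largest rises also lost their calls without FO isotype library 1 or 3 or FO 24 h library 2, all but Pla2g4a also without FO 24 h library 3, and all but Pla2g4a, Ppp2r2c and Hba-a1 without FO 24 h library 4. Cr2, Myc, Hspa1a, Socs3, Lcmt1, Timm22 and the Txnrd2 entries lost theirs without FO isotype library 3 or FO 24 h library 3, all but Myc also without FO 24 h library 2, Myc, Socs3, Lcmt1 and the Txnrd2 entries without FO isotype library 1, and these entries without FO isotype library 4. In all 1519 genes were called at 24 h, 743 higher and 776 lower. Without FO isotype libraries 1, 2, 3 and 4 in turn the count was 40, 2424, 25 and 2951, and without FO 24 h libraries 2, 3 and 4 it was 56, 78 and 382. It was 13 with the satellite covariate, 11 with only the groups compared, 5 with the FO libraries of at least 10% satellite share, 95 with the replicate number as a block, 2617 on log2 TPM with a pseudocount of 5 and 7175 without a filter on low values. Log2 TPM with a pseudocount of 1 gave 761 rises and 1507 falls, and satellite models left out of TPM gave 1134 and 240.

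At 48 h FO libraries still had lower Notch targets, and haemoglobin genes were higher. Hes1 fell by 1.22 to 22.7 ± 5.13 TPM (SE 0.171, adjusted p = 0.000228) and Dtx1 by 1.06 to 47.9 ± 9.04 (SE 0.0902, adjusted p = 3.2e-08, n = 4). S1pr3 (-0.96), Cdca7l (-1.14), Ell3 (-0.93), Fam129c (-0.91), Plac8 (-0.85), Rcc1 (-0.80), Bcap29 (-0.80) and Fcrl5 (-0.71) fell. The pair Hba-a1 (2.95) and Hba-a2 (2.80), which is uncertain, and Hbb-bs (2.76) and Hbb-bt (2.23) rose. Hbb-bs went from 62.7 ± 27.5 to 371 ± 96.6 TPM, and Wapal (1.14) and Cyfip1 (0.68) rose less. Of 7 Notch targets 3 fell, against 5 adjusted over the list alone (camera adjusted p = 4.12e-09; adjusted p = 0.00134 with an estimated correlation), with Hes5 at -0.87 (adjusted p = 0.0696). Also not called were Cr2 (-0.59), Nrarp (-0.33), Myc (-0.28), Cd1d1 (-0.24), Fcer2a (-0.12), Notch2 (0.24) and Cd93 (0.47), with adjusted p from 0.0757 to 0.561. Of 19 MZ markers 6 fell, against 12 adjusted over the list alone (adjusted p = 0.0187 with an estimated correlation), and of 9 markers of red cells and platelets 4 rose, against 6 adjusted over the list alone (camera adjusted p = 1.21e-08; adjusted p = 0.00774 with an estimated correlation). Whether the rises of red cell markers, here and in MZ libraries, came from B cells or from red cells in the samples was not tested.

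The satellite covariate ended the calls of Rcc1 (then -0.76, SE from 0.185 to 0.205), Fcrl5 (then -0.61, SE from 0.144 to 0.154), Bcap29 (then -0.57), Wapal (then 0.62) and Cyfip1 (then 0.44) in FO at 48 h, and with only the groups compared Hes1 was not called. These 5 genes and Cdca7l also lost their calls without FO isotype library 1 or 3 or FO 48 h library 1 or 3, Cdca7l and Rcc1 also without FO isotype library 2, and Cdca7l without FO 48 h library 2. There were 57 calls, 8 higher and 49 lower. Without FO isotype libraries 1, 2, 3 and 4 in turn there were 16, 118, 19 and 984, and without FO 48 h libraries 1, 2, 3 and 4 there were 15, 103, 19 and 427. The satellite covariate gave 16, only the groups compared 7, the FO libraries of at least 10% satellite share 9, the replicate number as a block 25, no mean-variance trend 37, sample weights 19, voom weights 29 and no filter on low values 321. Library medians set equal gave 8 rises and 24 falls, and satellite models left out of TPM gave 10 and 12.

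Whether the change from the isotype libraries of 48 h differed between MZ and FO cells was tested directly. At 12 h the fall of Dtx1 was larger in MZ by 1.23 (log2 difference of effects -1.23, SE 0.128, adjusted p = 2.58e-06), and the change was lower in MZ also for Tspan15 (-3.92), Hes5 (-2.42), Hes1 (-1.87), Asb2 (-1.81, with 0.62 in FO, adjusted p = 0.462) and Alpl (-1.77). Isotype FO libraries held 1.75, 8.43 and 4.81 TPM of Tspan15, Hes5 and Asb2, against 51.3, 91.9 and 114 in isotype MZ libraries. From such low levels a fall as large as in MZ could hardly be seen in FO. Dtx1 and Hes1, at 109 and 59.2 TPM in isotype FO libraries, had more room to fall. Mef2c, at 0.494 TPM in isotype MZ libraries (chromosome 13, 83504034 to 83667080, plus strand), had the largest difference in the other direction (4.21, SE 0.891, adjusted p = 0.0154), followed by Crisp3 (1.90), Abca1 (1.44), Stac2 (1.42) and Klf2 (1.30). Among MZ and FO sort markers the difference was -0.79 for Cd1d1 (chromosome 3, 86995834 to 86999441, minus strand) and 0.63 for Fcer2a (chromosome 8, 3681737 to 3694175, minus strand). For Myc it was -0.89, a call that ended without isotype MZ library 3 or 4, MZ 12 h library 2 or 3, FO isotype library 2 or 4 or FO 12 h library 1, 2 or 4. Not called were Cr2 (-0.37), Nrarp (-0.26), Notch2 (0.24) and Cd93 (0.78), with adjusted p from 0.549 to 0.844. Calls of Cd1d1, Fcer2a, Alpl and Stac2 ended without FO 12 h library 1, and those of Mef2c and Abca1 on log2 TPM scales. Alpl also lost its call without isotype MZ library 4, MZ 12 h library 1 or FO 12 h library 2, Stac2 without isotype MZ library 2, FO 12 h library 2 or MZ 12 h library 2, 3 or 4, and Fcer2a without any library of the 4 groups except isotype MZ 2, MZ 12 h 1, FO isotype 4 and FO 12 h 2 and 3. The change in MZ was lower than in FO for 5 of 7 Notch targets and 5 of 19 MZ markers, and higher for 8 of 12 FO markers, with the same counts adjusted over the list alone. Of 133 genes called, 73 had the higher change in MZ and 60 the lower. Without isotype MZ libraries 3 or 4 the count was 83 or 85, without MZ 12 h libraries 1 or 2 it was 82 or 85, without FO isotype library 2 it was 84 and without FO 12 h library 1 it was 70. It was 17 to 58 on log2 TPM scales (12 and 20 by direction with a pseudocount of 1), 71 without a filter on low values, and 231 to 307 with sample weights, equal medians, quantile normalization or satellite models left out.

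At 24 h and 48 h the same test, which compares changes and not levels, found a lower change in MZ than in FO for Tspan15, Hes5 and Ackr3 and a higher one for Lmna. Isotype FO libraries held 1.75, 8.43 and 1.32 TPM of Tspan15, Hes5 and Ackr3, against 51.3, 91.9 and 38.9 in isotype MZ libraries. Falls as large as in MZ could hardly be seen from such FO levels. At 24 h the differences of effects were -4.80 for Tspan15, -3.85 for Ackr3, -3.52 for Ube2e2, -2.89 for Hes5, -2.60 for Lair1, -1.87 for Hes1, -1.19 for Cd1d1 and -1.05 for Dtx1, and 1.01 for Fcer2a. Not called were Cr2 (-0.45), Myc (-0.31), Nrarp (-0.13), Notch2 (0.19) and Cd93 (0.72), with adjusted p from 0.568 to 0.972. Lmna (2.35), Crisp3 (2.35), Klf11 (2.03), Vim (1.88) and Emp3 (1.84) differed the other way, Ube2e2 lost its call without MZ 24 h library 4, and 4 of 7 Notch targets, 5 of 19 MZ markers and 8 of 12 FO markers were called, with the same counts adjusted over the list alone. Of 176 genes 126 had the higher change in MZ and 50 the lower. The count was 101 without MZ 24 h library 4, 114 without FO 24 h library 2, 395 with the satellite covariate, 112 with the replicate number as a block, 326 with sample weights, 283 with equal medians and 71 to 91 on log2 TPM scales with a pseudocount of 0.1 or 1, where 1 gave 51 and 40 by direction.

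At 48 h the differences of effects were -4.22 for Tspan15, -3.20 for Ackr3, -2.69 for Hes5, -2.49 for Ffar2, -2.26 for Rap1gap, -2.01 for Hes1, -1.61 for Dtx1, -1.44 for Cd1d1, -0.93 for Cr2 and -0.75 for Myc, and 0.52 for Fcer2a. Nrarp (-0.27), Notch2 (0.27) and Cd93 (1.75) were not called (adjusted p from 0.113 to 0.729). Myc lost its call without isotype MZ library 3 or 4, MZ 48 h library 1 or 2, FO isotype library 2 or 4 or FO 48 h library 2, 3 or 4, and Fcer2a without isotype MZ library 1, 3 or 4, MZ 48 h library 2 or 3, FO isotype library 2 or 3 or any 1 FO 48 h library. Positive differences of effects were 5.25 for Mef2c, 4.54 for Ces5a, 3.37 for Lmna, 3.14 for the scaffold gene Ahnak and 3.07 for Rab34. With the satellite covariate Ces5a stood at 2.38 and stayed called, and Rab34 at 1.43 and Myc at -0.56 lost their calls, as Rab34 did without FO isotype library 2. The change in MZ was below that in FO for 6 of 7 Notch targets, as for 6 adjusted over the list alone, and for 10 of 19 MZ markers, against 12 adjusted over the list alone, and above it for 7 of 12 FO markers, as for 7 adjusted over the list alone. Of 536 genes called, 232 had the higher change in MZ and 304 the lower. Without FO isotype libraries 1 or 2 there were 1280 or 314, without FO 48 h libraries 1 or 4 there were 877 or 352, and without isotype MZ library 3 and MZ 48 h library 1 there were 322. The satellite covariate gave 351 (269 called in both), and log2 TPM with a pseudocount of 1 gave 65 higher and 220 lower. Satellite models left out gave 375 and 243, quantile normalization 363 and 268, only the groups compared 267, and no filter on low values 323. The MZ and FO library of 1 number as a block gave 873.

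Differences among 12, 24 and 48 h were tested within each cell type. In MZ 2092 genes differed among the times and in FO 48. For MZ the count was 1321 without MZ 12 h library 2, 1351 without MZ 12 h library 3, 848 without MZ 48 h library 1, 1143 without MZ 48 h library 4 and 637 with the satellite covariate (611 called in both). It was 4110 to 4247 on log2 TPM scales, 3935 with sample weights, 1346 with the replicate number as a block, 1382 with satellite models left out and 914 without isotype library 3 and MZ 48 h library 1. For FO it was 24, 24, 930 and 18 without FO 12 h libraries 1, 2, 3 and 4 in turn, 74 without FO 48 h library 2 and 259 without FO 48 h library 4. Sample weights gave 1483 for FO, no filter on low values 695, equal medians 279, quantile normalization 218, a mean TPM of at least 5 gave 167 and satellite models left out 86. The replicate number as a block gave 27, and log2 TPM with a pseudocount of 1 or 0.1 gave 30 or 14. Genes called at both 24 h and 48 h in MZ with the same direction numbered 2014, of which 950 rose and 1064 fell. Simulated groups without effects against the same isotype libraries shared a median of 0 and at most 0 calls, a value that leaves out real effects and so does not measure what the shared libraries add, and independent lists of these sizes would share 205 rises and 330.3 falls. With the isotype libraries split between the comparisons 477 and 1390 calls were shared, and with the satellite covariate 300. Without isotype MZ library 3 the shared calls were 925, without MZ 24 h library 2 they were 695, without MZ 24 h library 3 they were 1156, and on log2 TPM with a pseudocount of 1 they were 1055.

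The change of MZ cells at 48 h was set beside the difference between FO and MZ cells under isotype. Over the 4284 genes that differed between the cell types, 3723 (86.9%) changed toward the FO value, against a mean of 50.1% (highest 51.7%) in simulated groups without effects, 84.2% and 87.8% with the isotype MZ libraries split between the comparisons, and 85.6% of the genes called with the satellite covariate. The genes were chosen once with all isotype MZ libraries and kept in the draws and splits, so neither measures what that choice adds. Satellite share was also lower in isotype MZ (2.65%) than in isotype FO (12.4%) and MZ at 48 h (35.3%), so both differences hold that component. The correlation across these genes, which are not independent replicates, was 0.784 and the covariance 1.18. Both comparisons use the isotype MZ libraries, and simulated groups without effects gave a correlation of 0.11 and a covariance of 0.0435 (highest 0.0781), so the covariance exceeded the simulated one by 1.13. The draws gave each gene independent noise. Their highest share and covariance therefore do not measure the spread for genes that move together. With the isotype MZ libraries split between the comparisons the correlation was 0.759 and 0.694 and the covariance 1.14 and 1.10. With the satellite covariate the correlation over 2927 genes was 0.784 and the covariance 0.895.

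**Figure D3:**
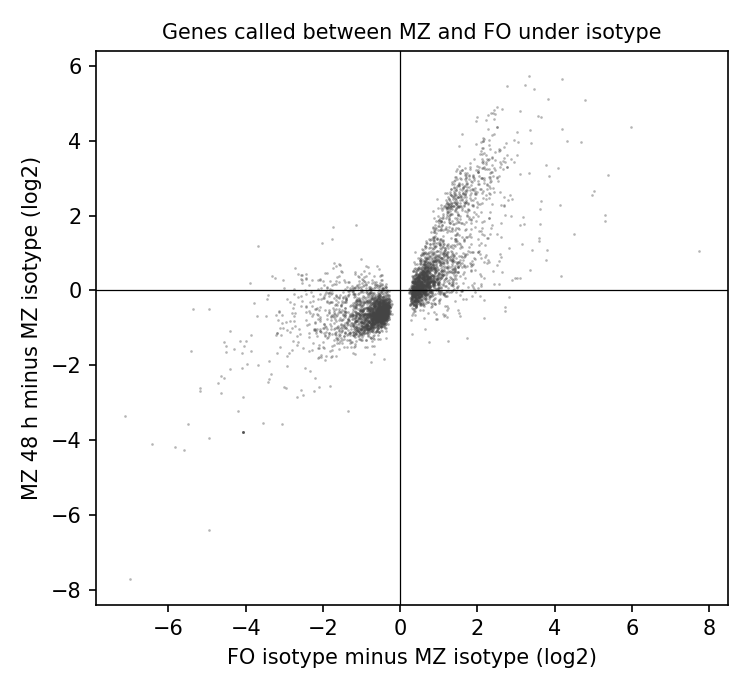
Log2 difference of MZ at 48 h minus isotype MZ (y axis) against the log2 difference of isotype FO minus isotype MZ (x axis), with a dot for each of 4284 genes called between the cell types under isotype. Of these genes 3723 lie toward the FO value, and the correlation across genes is 0.784.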

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

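The tests of explanations for the first 3 patterns in this part were chosen after the results were seen, and the counts of other splits of the libraries and the direct tests of the MZ effect against the FO effect were not. Of 271 groups of 4 values examined, 19 held 1 library far from the others, and chance alone gives such a gap in about 1 group in 20.

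The summed satellite models, a signal outside the comparisons of genes, lay above their level in every isotype library of the same cell type, at 10.2% of listed TPM in MZ at 12 h, 17.0% at 24 h and 35.3% at 48 h, and at 31.9% in FO at 24 h. Transcription of the satellite repeats alone would leave olfactory receptor genes level, but their summed TPM was 6.13 times as high in MZ at 48 h as under isotype, and a smaller library total is excluded as the whole cause because the ratio of totals was 0.9996 at 12 h. Genomic DNA in the libraries may account for the signal, since log2 satellite share and log2 olfactory TPM, centred within groups, rose together across the 15 FO libraries (r = 0.970, permutation p = 3e-05; rho = 0.979, permutation p = 1e-05, the smallest that 100000 permutations can give; r = 0.951 without the 2 libraries farthest from the median). Across the 15 MZ libraries, the other of 2 relations computed, r was 0.921 (permutation p = 0.00018) and rho 0.918 (permutation p = 0.00053), with r at 0.824 without the 2 farthest, and adjusted p-values were 6e-05 and 2e-05 for FO and 0.00018 and 0.00053 for MZ. The 2 signals did not rise in proportion. In MZ the satellite share rose 3.86, 6.40 and 13.3 times at 12, 24 and 48 h, and olfactory TPM 1.85, 3.34 and 6.13 times. In FO at 24 h the satellite share rose less, 2.57 against 3.31 times. Transcription of the repeats in addition to DNA was therefore not excluded. Whether the antibody raised the DNA content was not tested and stays open as a biological explanation.

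Genes higher in MZ at 48 h followed the satellite share in a separate set of libraries. Of the 1619 called genes under 5 TPM in isotype MZ libraries, 93.8% had a positive slope on satellite share across FO libraries, against 65.9% of 2281 uncalled genes at that level, so DNA in the libraries may account for many of these rises. Of the 735 called genes of at least 5 TPM, 71.2% had a positive slope, against 38.4% of 4346 uncalled genes and 9.83% of 3733 genes that fell. The median slope was -0.099 in those that fell and -0.031 in the uncalled genes, so the falls went with satellite share too. For these rises and falls as sets, an effect of the antibody and DNA in the libraries cannot be told apart. In MZ the satellite share rose with treatment in every library, and across all genes the FO slope and the MZ change correlated at 0.722. Lmna (4.17, and 4.24 with the satellite covariate) is a rise that this covariate did not lower.

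Notch target genes fell in treated MZ cells beyond what dilution by the satellite models would give, since their median change at 48 h was -2.49 with the satellite covariate and this dilution amounts to -0.59 by share of TPM and -0.23 by share of estimated counts. Dilution by other DNA reads was not measured, but as the whole cause it would lower abundant genes alike, and the median of 38 ribosomal protein genes fell by 0.91. FO cells in the MZ gate are also excluded as the whole cause. The 20 genes at least 8-fold higher in FO than in MZ cells imply a median FO share of 14.2% (quartiles 3.21% and 29.4%), whereas the fall of Dtx1 would need 94.3%. A fall in Notch2 signalling, which the design names, is consistent with these values and remains a hypothesis, since the other explanations were tested on the libraries that show the fall.

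Other splits of the same libraries were counted for each comparison. For MZ at 12 h, 24 h and 48 h and for MZ against FO, 1 of 35 splits, the real one, gave as many calls (1279, 2217, 6195 and 4284 calls, against at most 2, 588, 42 and 1295 in the others). A share of 1 of 35 is the smallest that this count can give, and no share here was adjusted over the 12 comparisons. These counts argue against chance there without excluding it. Chance was not excluded for FO at 12 h (4 of 35 splits as large, 26 calls, highest other 1713), 24 h (3 of 35, 1519 calls, 2673) or 48 h (3 of 35, 57 calls, 1709). The splits with the most calls at 12 and 48 h set FO isotype libraries 1 and 3, with satellite shares of 1.75% and 3.95%, together with treated libraries 2 and 4. Those had 5.77% and 13.3% at 12 h, against 22.1% and 24.9% in libraries 1 and 3, and 24.0% and 13.8% at 48 h, against 45.0% and 31.6%. At 24 h the highest count came from setting isotype libraries 1, 2 and 3 apart, whose shares lay below those of the other libraries. Such counts, many times the real one at 12 and 48 h, point to a structure of the FO samples beyond the treatment, which went with satellite share in these splits. For the differences between the MZ and the FO effect, 4 of 100 drawn splits, the real one included, were as large at 12 h (133 calls, highest other 328). At 24 h it was 4 of 100 (176 calls, 3646) and at 48 h 8 of 100 (536 calls, 6708). For differences among times 1 of 100 drawn splits was as large in MZ, the real one (2092 calls, highest other 1468), and 3 of 100 in FO (48 calls, 931). In the 3 drawn splits with the most calls for each difference of effects, the MZ isotype and treated libraries stayed whole as groups, or traded places whole. The real MZ effect therefore entered these counts. They cannot decide whether chance explains the differences of effects at any time, and they do not show a structure of the samples by themselves. In FO among times the 2 splits with the most calls (931 and 623) kept FO 12 h libraries 1, 2 and 4 together and apart from library 3. The real difference between 12 h and later libraries therefore entered these 2 counts. With the true groups, 930 genes were called without FO 12 h library 3. The 2 splits do not show a structure of the FO samples by themselves. In the split with 931 calls FO 12 h libraries 1, 2 and 4 stood with FO 48 h library 4, at satellite shares of 5.77% to 22.1%, against 24.0% to 45.0% in the other libraries.

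Single libraries far from the other 3 of their group, in log2 CPM, were isotype MZ library 3 for Notch2 (5.84), Olfr613 (2.92), Glrb (2.5), Fgd4 (5.75), Hsd3b2 (3.63), Khdrbs2 (-1.94) and Pde2a (-4.20). This library also had the lowest satellite share of the MZ libraries (0.227%). Others were MZ 12 h library 2 for Irgm2 (-3.64), MZ 12 h library 1 for Ccdc79 (2.24), MZ 48 h library 4 for Pgam1-ps2 (-2.54) and MZ 48 h library 1 for Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6 (-1.61 each). In FO they were isotype library 4 for Hes5 (2.10) and for the entries Txnrd2 and TXNRD2 (4.27 each), and FO 48 h library 1 for Cd93 (3.8). FO 48 h library 3 had a total of 6.03 estimated counts in units of 1000000, below the other libraries of its group.

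The change from isotype differed between MZ and FO, by a direct test on the log2 scale, for the named genes below. At 12 and 24 h the antibody and the sampling time cannot be told apart, since isotype libraries were taken at 48 h. Among the named genes Tspan15, Ackr3, Rap1gap, Asb2 and Hes5 had little room to fall in FO. Isotype FO libraries held 1.75, 1.32, 1.53, 4.81 and 8.43 TPM of them. At 12 h the log2 difference of effects was -1.23 for Dtx1, -0.89 for Myc, -0.79 for Cd1d1, 0.63 for Fcer2a, -3.92 for Tspan15, -2.42 for Hes5, -1.87 for Hes1, -1.81 for Asb2, -1.77 for Alpl, 1.30 for Klf2, 1.42 for Stac2, 1.44 for Abca1, 1.90 for Crisp3 and 4.21 for Mef2c. The 24 h values were -1.87 for Hes1, -1.19 for Cd1d1, -1.05 for Dtx1, 1.01 for Fcer2a, -4.80 for Tspan15, -3.85 for Ackr3, -3.52 for Ube2e2, -2.89 for Hes5, -2.60 for Lair1, 1.84 for Emp3, 1.88 for Vim, 2.03 for Klf11, 2.35 for Crisp3 and 2.35 for Lmna. At 48 h they were -2.01 for Hes1, -1.61 for Dtx1, -1.44 for Cd1d1, -0.93 for Cr2, -0.75 for Myc, 0.52 for Fcer2a, -4.22 for Tspan15, -3.20 for Ackr3, -2.69 for Hes5, -2.49 for Ffar2, -2.26 for Rap1gap, 3.07 for Rab34, 3.14 for Ahnak, 3.37 for Lmna, 4.54 for Ces5a and 5.25 for Mef2c. The calls of Myc and Fcer2a at 12 and 48 h each ended without several single libraries, isotype MZ libraries 3 and 4 among them, and those of Myc (-0.56) and Rab34 (1.43) at 48 h also ended with the satellite covariate, with which Ces5a stood at 2.38. Calls of Cd1d1, Alpl and Stac2 at 12 h ended without FO 12 h library 1, and those of Mef2c and Abca1 at 12 h on log2 TPM scales. Ube2e2 lost its call at 24 h without MZ 24 h library 4.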

How the results depend on the processing

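The satellite covariate, the removal of satellite models, voom weights and the subsets by satellite share were tests chosen after the data were seen, and the other alternatives were fixed in advance. Apart from single libraries left out, counts of calls and summary values stayed within 1.5 times or 1 SD in 121 cases and moved in 76. For named genes and lists 4202 values kept their direction and side of the threshold, 446 lost a call, 21 gained one and 9 reversed. With 1 library left out these numbers were 2065, 243, 7 and 0 for genes and lists, and 99 summary values stayed and 53 moved. Where no construction of the alternative shows it, the cause was not tested. Low genes were harder to call, since for MZ at 48 h a simulated log2 change of 1 was recovered in 8.33% of 24 genes under a mean of 5 TPM and 81.1% of 53 genes at or above it, and how much of this is due to depth was not tested. Count models were not run because the estimated counts are not whole.

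Log2(TPM + 1) gave 586 calls for MZ at 12 h, 1155 at 24 h, 32, 91 and 285 for the differences of effects at 12, 24 and 48 h, 4247 and 30 among times in MZ and FO, 1055 shared calls and a correlation of the MZ shift of 0.758. Log2(TPM + 0.1) gave 582, 1262, 17, 71, 237, 4110 and 14 for the first 7 of these. Log2(TPM + 5) gave 653 and 1096 for MZ at 12 and 24 h, 2617 for FO at 24 h, 58 for the difference at 12 h and 4185 among times in MZ. No filter on low values, which tests more genes, gave 9575 for MZ at 48 h, 7175 and 321 for FO at 24 and 48 h, 71 and 323 for the differences at 12 and 48 h and 695 among times in FO, and a mean TPM of at least 5 gave 167 for the last and a shift of 0.758. No mean-variance trend gave 37 for FO at 48 h and voom weights 29. Sample weights gave 2114 and 3533 for MZ at 12 and 24 h, 19 for FO at 48 h, 231 and 326 for the differences at 12 and 24 h and 3935 and 1483 among times in MZ and FO. Equal medians gave 32 for FO at 48 h, 255 and 283 for those differences and 279 among times in FO, and quantile normalization 291 for the difference at 12 h and 218 among times in FO. Only the groups compared, with fewer samples for the spread, gave 9, 11 and 7 for FO at 12, 24 and 48 h and 267 for the difference at 48 h. An estimated correlation between genes left 21 of 90 list calls.

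The satellite covariate gave 757, 431 and 672 for MZ at 12, 24 and 48 h, 13 and 16 for FO at 24 and 48 h, 395 and 351 for the differences at 24 and 48 h, 637 among times in MZ and 300 shared calls. It reversed Cd93 in MZ at 24 h (-0.0337), and at 48 h Notch2 (-0.14), Olfr613 (-0.23), Glrb (-0.41), Hsd3b2 (-0.42) and Khdrbs2 (-1.04), as well as the medians of ribosomal protein genes at 12 h in MZ (0.0231) and FO (0.0355) and of oxidative phosphorylation in FO at 12 h (0.0554). Satellite models left out gave 22 for FO at 48 h, 307 for the difference at 12 h and 1382 and 86 among times in MZ and FO. Without both MZ libraries of extreme satellite share there were 1128 calls for MZ at 24 h, 322 for the difference at 48 h and 914 among times in MZ. FO libraries of at least 10% satellite share, with fewer samples, gave 15, 5 and 9 for FO at 12, 24 and 48 h. The median change of all genes in MZ at 48 h was -0.13, and -0.37 on log2(TPM + 1), 0.00 with equal medians and 0.16 with satellite models left out.

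The replicate number as a block within cell type gave 95 and 25 for FO at 24 and 48 h, 1530 for MZ against FO, 112 for the difference at 24 h, 1346 and 27 among times in MZ and FO and a shift of 0.753, and the MZ and FO library of 1 number as a block gave 873 for the difference at 48 h. The labels do not say that a number marks a shared mouse, and the pairing check gave correlations of -0.0412 to 0.232 over 15 pairs between cell types, 4 of them over 0.1 and 9 best with their own number. By chance a library would match its own number in 1 of 4 cases, or 1 of 3 at 24 h, so 9 of 15 is above that rate. MZ and FO libraries of 1 number may thus share a mouse, which stays open. Over 22 pairs of isotype and treated libraries the correlations ran from -0.337 to 0.187, with 1 over 0.1 and 3 best with their own number. Calls lost under the block within cell type are therefore not read as weaker effects.

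With each library left out in turn, calls ranged from 776 to 1145 for MZ at 12 h, 804 to 2076 at 24 h and 5394 to 5943 at 48 h, and from 14 to 23, 25 to 2951 and 15 to 984 for FO. They ranged from 3230 to 4876 for MZ against FO, 70 to 196, 101 to 189 and 314 to 1280 for the differences of effects, 848 to 2488 and 18 to 930 among times in MZ and FO and 695 to 2259 for shared calls. The shift ranged from 0.749 to 0.846.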

Other observations

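The gene lists in this part were fixed before the data were examined, and the values with the satellite covariate come from tests chosen after the results were seen. In treated MZ cells, genes of sterol synthesis were higher at 48 h. Of 21 tested, 10 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00432; adjusted p = 0.508 with an estimated correlation). The receptor gene Ldlr rose by 1.83, Hmgcs1 by 1.21, Sqle by 1.04, Insig1 by 0.76 and Idi1 by 0.64, and 6 of the 21 rose with the satellite covariate. At 24 h 2 of 21 rose, as did 2 adjusted over the list alone, with Ldlr at 1.17 and Hmgcs1 at 0.79 (camera adjusted p = 0.0613). Interferon response genes went the other way at 48 h. Of 24 tested 13 fell and 1 rose, against 14 and 1 adjusted over the list alone (camera adjusted p = 0.00779; adjusted p = 0.453 with an estimated correlation), and 1 fell with the satellite covariate. Isg15 fell by 1.39, 1.65 and 1.79 at 12, 24 and 48 h, and Ifit3 by 1.02 at 48 h. Of 8 markers of B1 cells, 2, 3 and 4 rose at 12, 24 and 48 h and 1 fell at 48 h, against 2, 5 and 4 rises and 1 fall adjusted over the list alone (adjusted p = 0.322, 0.141 and 0.253 with an estimated correlation). Anxa2 rose by 1.19, 1.59 and 2.00 at these times and Bhlhe41 by 0.54, 0.71 and 0.88.

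Survival and migration genes of MZ cells changed in both directions. Of 17 BCL2 family and survival genes 4 rose and 2 fell at 12 h, 6 and 3 at 24 h and 6 and 5 at 48 h, against 5 and 3, 6 and 4, and 6 and 6 adjusted over the list alone (camera adjusted p = 0.18, 0.253 and 0.63). Bcl2 rose by 0.71, 0.62 and 0.52 and Mcl1 by 0.47, 0.43 and 0.31, while Bcl2a1d fell by 0.76 at 48 h. Of 24 migration and retention genes 6 rose and 7 fell at 12 h, 7 and 6 at 24 h and 6 and 7 at 48 h, against 7 and 7, 7 and 6, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.853, 0.936 and 0.871). The chemokine receptor gene Cxcr4 rose by 0.67, 0.97 and 1.41 and Sell by 0.56, 0.78 and 0.49, and S1pr1, needed for exit from lymphoid tissue, fell by 0.95, 0.82 and 1.01. Of 26 B cell identity genes 4 rose and 2 fell, then 4 and 5, then 3 and 12, against 5 and 4, 4 and 5, and 3 and 13 adjusted over the list alone (camera adjusted p = 0.217, 0.973 and 0.123). Bach2 rose by 0.98, 1.21 and 0.88, and Cd22 fell by 0.42, 0.55 and 0.80. Of 21 NF-kB targets 10 fell at 48 h, as did 10 adjusted over the list alone, with Icam1 at -1.09 and Cd40 at -0.90 (camera adjusted p = 0.0175; adjusted p = 0.529 with an estimated correlation).

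Secretory pathway genes fell in 6, 10 and 15 of 37 cases in MZ at 12, 24 and 48 h, against 8, 10 and 15 adjusted over the list alone (adjusted p = 0.371, 0.523 and 0.691 with an estimated correlation). The chaperone gene Hspa5 fell by 0.69, 0.53 and 0.51. Of 17 plasma cell genes 1 rose and 2 fell at 12 h, 0 and 3 at 24 h and 3 and 6 at 48 h, against 1 and 4, 0 and 3, and 3 and 6 adjusted over the list alone (adjusted p = 0.489, 0.743 and 0.987 with an estimated correlation). Of 23 genes of amino acid supply and ATF4 targets 6 fell at 12 h, against 9 adjusted over the list alone (camera adjusted p = 0.00238; adjusted p = 0.276 with an estimated correlation). Of 22 Notch pathway components 1 rose and 1 fell, then 5 and 1, then 3 and 6, with the same counts adjusted over the list alone (camera adjusted p = 0.472, 0.622 and 0.842).

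Markers of other cells in MZ libraries at 48 h had these counts. Of 14 T cell markers 2 were higher and 3 lower, against 1 and 0 adjusted over the list alone (camera adjusted p = 0.646). Dendritic cell markers were higher in 3 of 7 cases, as were 3 adjusted over the list alone (camera adjusted p = 0.226). NK cell markers were lower in 2 of 7 cases, against 1 adjusted over the list alone (camera adjusted p = 0.958). Transitional B cell markers were higher in 1 and lower in 2 of 6 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.953). The 1 stromal marker tested was not called, also adjusted over the list alone (camera adjusted p = 0.493). In MZ against isotype, medians, means and tests differed in sign for migration genes at 12 and 24 h, dendritic cell markers at 12 h, B cell identity and immediate early genes at 24 h, and plasma cell, survival, T cell, myeloid and transitional B cell genes at 48 h.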
